A study of Mus musculus with 12 samples.

How the data were processed

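RNA was measured in 12 libraries of mouse bone marrow progenitors in 4 groups of 3. Cells sorted for surface c-Kit and Sca-1 and depleted of lineage markers (a stem- and progenitor-rich fraction) were grown in RPMI with IL-3 and IL-6 at 20 ng/ml each and SCF at 100 ng/ml. They received a retroviral MSCV vector, either empty or carrying NUP98-NSD1, a fusion of a nucleoporin with a histone H3 lysine 36 methyltransferase that is found in acute myeloid leukaemia. A pLKO.1 lentiviral vector added a control shRNA or 1 of 2 shRNAs against Nizp1, a zinc finger protein that binds NSD1. Nizp1 is listed under its symbol Zkscan17 in the file.

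Per the labels' protocols, libraries were made from 1 µg of RNA with a stranded poly(A) kit and read as single 75 nt reads. The deposited values are whole-number counts of reads per gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.5.3a to mm10 and counted with featureCounts, whose version, strand setting and annotation release are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene may not have been told apart. Reads mapping to near-identical copies may have been left out or split, so values of Cstdc4, Cstdc5, Stfa2l1, the Mcpt and Ear families, C4a and the H2 genes are uncertain. The file lists 55376 genes, 31694 of them with no count in any library. Coordinates are those of the file (mm10), and 48708 genes (88.0%) have the start, end and strand of the GENCODE vM21 annotation of that build, while 866 symbols are not found in it.

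Total counts ran from 3586538 to 6842589 per library, so that 3 counts correspond to between 0.417 and 0.837 CPM (counts scaled to the counts over the tested genes times the TMM factor). Lower bounds on folds against a group with no count use 3 counts over the group, and ratios with 1 to 3 counts carry 95% exact binomial intervals. Reads carry no molecular identifiers, so these intervals and floors cover counting error only. The series describes independent experiments but does not name animals, and p-values measure the spread between these libraries.

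The main test was the quasi-likelihood test of edgeR 4.0.16 with R 4.3.3 (robust), fitted to all 12 libraries with 1 mean per group, after filtering low counts on the group design (11994 genes tested) and TMM scaling. Benjamini-Hochberg adjusted p-values had to lie under 0.05. With no effect, a share of 0.05 of the tested genes would have an unadjusted p under 0.05. The unblocked counts of such genes given below lie under or near that share. SEs were derived from the F statistic. The replicate number was not in this model, because the labels do not say that it marks an experiment. Residuals then showed that it pairs the samples: libraries with the same number correlated in all 18 pairs (r between 0.20 and 0.87, median 0.74), against a median of -0.18 for other pairs. All 12 libraries correlated best with a library of their own number. The first principal component held 60.6% of the variance, and the replicate number explained 96.9% of it. Values from a fit with the replicate number as a block therefore stand beside the unblocked ones (a value of a gene or list is blocked unless the text says otherwise), and libraries sharing a number are called an experiment, which is an inference. The pairing was decided from these correlations, not from the calls. In the blocked fit, 1319 genes had an unadjusted p under 0.05 with the fusion and 1479 with shNizp1#1. Such genes numbered 1331 with shNizp1#2 and 1779 between the shRNAs, each above the share of 0.05 of tested genes. No pair of replicates agreed within sampling noise.

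Genes were named by a rule: Zkscan17, Nup98 and Nsd1 always, then in each comparison the 10 called genes with the largest positive and the 10 with the largest negative change (5 and 5 between the shRNAs) among genes with at least 5 CPM in the higher group, no overlap of the groups and a symbol that is not a predicted or clone name. Up to 4 called members of each list were also named, or the 2 most highly expressed where none was called. In the blocked fit, "no overlap" was replaced, after the data were seen, by the same direction in all 3 pairs. For list members no such condition applied. A gene that met the rule is not reported here.

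There were 27 gene lists, with 540 entries of which 539 were in the file (Ahsp was missing) and 422 were measured. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 3 measured members had no list test. Groups, comparisons, lists, the naming rule, the tests and the first set of alternatives were fixed before the data were examined. The blocked counterparts of the alternatives, the fit without experiment 3 and the tests of 3' UTR words were added later.

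Alternatives were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared and leaving out each library. Against shared control libraries, 100 data sets with no group effect were simulated. Each gene was drawn independently of the others, so correlation between genes is missing from the simulated spread. Controls of 3 libraries cannot be split, so part of any excess over the simulated values may come from the shared controls. The test was tried on simulated counts with 200 changed genes. In the simulated fusion comparison (11882 genes), the unblocked fit recovered 2.99% of genes changed 1.5-fold, 29.9% changed 2-fold and 74.2% changed 4-fold. The blocked fit recovered 41.8%, 79.1% and 93.9%, with 4 unchanged genes called. In the simulated comparison of the first shRNA (11861 genes), the blocked fit recovered 40.3%, 83.6% and 89.4%, with 12 unchanged genes called.

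The 3' UTR of each gene was the longest in vM21. Each 7-base word present in at least 50 UTRs was regressed on blocked log2 fold changes with UTR length and GC content as covariates. Of 10176 tested genes with a mean of at least 5 CPM, 9773 (96.0%) had a 3' UTR of at least 50 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.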

Results

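The data are read counts per gene in 4 groups of 3 libraries. The first group carried the empty vector and the control shRNA, the second NUP98-NSD1 and the control shRNA, and the remaining groups NUP98-NSD1 with shNizp1#1 or with shNizp1#2. Totals were 5977514, 4096524 and 4468392 counts in the empty-vector libraries and 4708272, 5436903 and 4937646 with the fusion and the control shRNA. They were 4247364, 3586538 and 6842589 with shNizp1#1 and 6376573, 6454564 and 6661275 with shNizp1#2. According to its title, the series asks whether Nizp1 works together with NUP98-NSD1. The comparisons are therefore the fusion against the empty vector, each shRNA against the control shRNA in fusion cells, and the shRNAs against each other. All 4 groups expressed mast cell genes at a high level: the mast cell list held between 4.99% and 7.22% of the counts of every library, and Cpa3, the mast cell carboxypeptidase, averaged 25730 ± 4768 CPM (SD, n = 3) with the empty vector and 25281 ± 4239 with the fusion.

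Zkscan17, the gene of Nizp1 (chromosome 11, 59485520 to 59506644, minus strand), was lower in every library with a targeting shRNA than in every library with the control shRNA. It averaged 63.1 ± 5.69 CPM (SD, n = 3) with the empty vector, 57.9 ± 7.42 with the fusion and the control shRNA, 30.5 ± 4.37 with shNizp1#1 and 24.5 ± 6.08 with shNizp1#2. With the replicate block, edgeR gave a log2 fold change of -0.93 (SE 0.12, adjusted p = 0.00198) for shNizp1#1 and of -1.25 (SE 0.12, adjusted p = 2.90e-04) for shNizp1#2. Without the block neither was called (adjusted p = 0.490 and 0.228). Between the shRNAs, Zkscan17 differed by -0.32 (SE 0.13, adjusted p = 0.230, blocked), lower with shNizp1#2 in 3 of 3 experiments. Both blocked decreases of Zkscan17 were called with each single library left out. The shNizp1#1 decrease was not called when experiment 3 was left out (-0.88). The fusion itself left Zkscan17 uncalled (log2 fold change -0.13, adjusted p = 0.728, blocked).

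**Figure D1:**
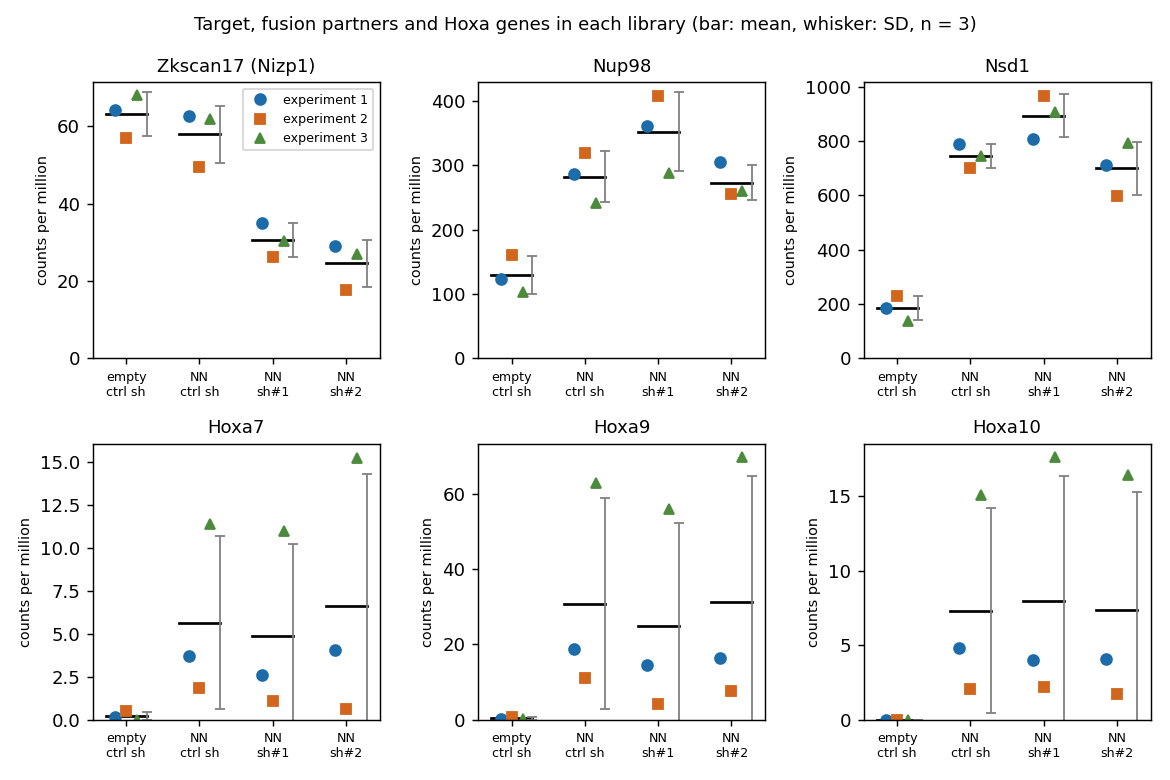
CPM of Zkscan17, Nup98, Nsd1, Hoxa7, Hoxa9 and Hoxa10 in each of the 12 libraries, by group on the x axis (NN is NUP98-NSD1) and by experiment in colour and shape, with the mean as a bar and the SD as a whisker (n = 3, drawn from 0 upwards). Zkscan17 averaged 30.5 and 24.5 CPM with the targeting shRNAs, and Hoxa9 was highest in experiment 3 in each group that carried the fusion.

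With NUP98-NSD1, genes of the HoxA cluster went from near absence to clear expression. Hoxa9, a homeobox factor of stem cell self-renewal (chromosome 6, 52223100 to 52227370), rose from 0.380 ± 0.318 CPM (SD, n = 3) to 30.9 ± 27.9, a log2 fold change of 6.42 (SE 0.50, adjusted p = 2.42e-04 in edgeR with the replicate block). Its neighbour Hoxa10 (52231197 to 52240854) went from 0 to 110 counts over the group, at least 34.9-fold higher (adjusted p = 3.06e-04). Hoxa7 (52214498 to 52218711) went from 3 to 85 counts, a ratio of 26.9 (95% interval 8.91 to 133, adjusted p = 0.0267). The Hoxa9 levels of the fusion libraries were 18.8, 11 and 62.8 CPM in experiments 1, 2 and 3. Hoxb4 was at 5.04 ± 1.58 CPM against 5.16 ± 1.05, and Hoxb3 at 1.98 ± 1.17 against 0.118 ± 0.204, neither of them called (adjusted p = 0.976 and 0.176).

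Both partners of the fusion were higher as well. Nsd1 (chromosome 13, 55209782 to 55318325) rose from 185 ± 45.6 to 744 ± 44.4 CPM and Nup98 (chromosome 7, 102119398 to 102210176) from 129 ± 29.5 to 282 ± 39.3. The blocked log2 fold changes were 2.01 (SE 0.17, adjusted p = 4.90e-04) and 1.14 (SE 0.12, adjusted p = 3.98e-04). Reads of the construct can be counted in both genes, so these values do not measure the endogenous genes alone.

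Outside the HoxA cluster, the genes with the largest increases included Kcnc1, a voltage-gated potassium channel, with 235 counts against 2 (ratio 112, interval 30.6 to 928), most of them in experiment 3: Kcnc1 was at 4.60, 0.373 and 41.6 CPM with the fusion against 0, 0.249 and 0.217 in experiments 1, 2 and 3. Dkk2, a secreted regulator of Wnt signalling, rose by 3.92 in log2 (SE 0.67, adjusted p = 0.0267). Bcl11a, a zinc finger repressor of blood cell development, rose by 2.28 (SE 0.39, adjusted p = 0.0267). Peli3, Rbms3 and Cxxc5 rose by 4.08, 3.82 and 2.11, with Peli3 at 0.746 against 0.498 CPM in experiment 2. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 0.79 (adjusted p = 0.0417). Avil, an actin-binding protein, and Cdkn2d, an inhibitor of cyclin-dependent kinases, were lower by -0.69 and -0.54 (adjusted p = 0.0359 and 0.0351). Kit (log2 fold change -0.19, adjusted p = 0.482), Cpa3 (-0.02, adjusted p = 0.946) and the mast cell protease Cma1 (-0.47, adjusted p = 0.193) were not called.

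Without the replicate block, edgeR called 1 gene higher with the fusion, Nsd1 (adjusted p = 0.00375), and 0 lower. DESeq2 called 8 higher and 0 lower, and limma-voom 1 and 0. At an unadjusted p under 0.05 there were 320 genes, fewer than the share of 0.05 of tested genes that no effect would give. The blocked fit had 1319 such genes, more than that share. With the block 30 genes were higher and 3 lower, 24 and 0 of them with an absolute log2 fold change of at least 1. Leaving out 1 library moved the blocked counts of higher genes to 80, 75 and 5 without empty-vector replicates 1, 2 and 3, and to 26, 15 and 4 without fusion replicates 1, 2 and 3. The corresponding counts of lower genes were 10, 94 and 0, and 1, 1 and 0. Hoxa9, Hoxa10, Nsd1 and Nup98 were called in each of these 6 fits, and the other genes named here, Hoxa7 among them, lost the call in at least 1. With all of experiment 3 left out, the blocked fit called 2 genes in all, so Hoxa9, Hoxa10, Nsd1 and Nup98 did not all keep the call. Of the 33 blocked calls, 26, 33 and 5 kept theirs without empty-vector replicates 1, 2 and 3, and 14, 15 and 4 without fusion replicates 1, 2 and 3.

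Among the gene lists, in the blocked fit, all 3 measured HoxA genes were called higher with the fusion (also adjusted over the list alone), with a median log2 fold change of 6.42, or 5.12 with Hoxa10 at its bound and Hoxa7 at its ratio. The list test gave camera adjusted p = 3.16e-39, and adjusted p = 0.00459 with an estimated correlation. Genes of dendritic cells and MHC class II (antigen presentation) shifted upwards together: 11 of 11 lay above 0, with a median of 1.12 and camera adjusted p = 1.35e-10, and adjusted p = 0.0249 with an estimated correlation. None of these 11 was called over all genes, and 7 were called adjusted over the list alone. The invariant chain Cd74 was at 21.9, 192 and 4.12 CPM with the fusion against 27.7, 72.6 and 5.21 with the empty vector in experiments 1, 2 and 3, so it was higher in experiment 2 alone. Leukaemia self-renewal regulators lay higher (15 of 22 above 0, median 0.24, 6 called adjusted over the list alone, camera adjusted p = 0.00108), with adjusted p = 0.0511 with an estimated correlation. HoxB genes had 2 measured members and the HoxC and HoxD list 0, too few for a list test.

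Interferon-stimulated genes lay above 0 in 26 of 26 members with the fusion, by a median of 1.15 (camera adjusted p = 2.74e-05, and adjusted p = 0.812 with an estimated correlation). That shift came from experiment 2, where the mean log2(CPM + 1) of the list was 5.03 with the empty vector and 6.62 with the fusion. Without fusion replicate 2 its adjusted p was 0.379, and in the unblocked fit the direction turned. Monocyte genes (median 0.45, adjusted p = 0.00146), megakaryocyte genes (-0.34, 0.00719), G2 and M phase genes (-0.16, 0.00963), ribosome biogenesis genes (0.10, 0.0470) and cholesterol synthesis genes (-0.15, 0.0475) also passed camera. With an estimated correlation the adjusted p was 0.610 for megakaryocyte genes and 0.812 for the other 4 lists. Each of these 5 lost its call when at least 1 library was left out. Monocyte genes did without empty-vector replicates 2 and 3 and fusion replicate 2 (adjusted p = 0.0552, 0.276 and 0.183), megakaryocyte genes without empty-vector replicate 1 (0.121), and G2 and M phase genes without empty-vector replicate 2 and fusion replicates 1 and 3 (0.707, 0.101 and 0.149). Cholesterol genes did without empty-vector replicates 2 and 3 and fusion replicate 1 (0.723, 0.430 and 0.773), and ribosome biogenesis genes without all but empty-vector replicate 2 (between 0.0542 and 0.836).

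Without the block, camera gave adjusted p = 8.01e-14 for HoxA genes, 2.27e-06 for dendritic cell and MHC class II genes, 0.00995 for both leukaemia regulators and G2 and M phase genes, and 0.00850 for interferon-stimulated genes. That interferon value was 0.0959 in limma-voom, 0.943 with an estimated correlation, and 0.236 and 0.536 without empty-vector replicates 1 and 3. Over all comparisons, an estimated correlation ended 15 of the unblocked list calls. Monocyte (0.0593), cholesterol (0.0776), megakaryocyte and ribosome biogenesis genes (0.0931 for both) did not pass without the block. The other lists did not pass camera in the blocked fusion comparison. Their adjusted p-values were 0.147 for stem and progenitor genes, 0.691 for primary granule genes, 0.227 for neutrophil maturation genes, 0.277 for mast cell genes, 0.555 for eosinophil genes and 0.277 for erythroid genes. B cell, T and NK cell, and stromal genes were at 0.680, 0.832 and 0.680, S phase genes at 0.17 and the p53 list at 0.680. Glycolysis, stress response, immediate early and cytokine genes were at 0.849, 0.905, 0.247 and 0.639, and the list of fusion partners and histone methylation genes at 0.277. In the stromal list, the mean lay above 0 and camera gave the direction as down.

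**Figure D2:**
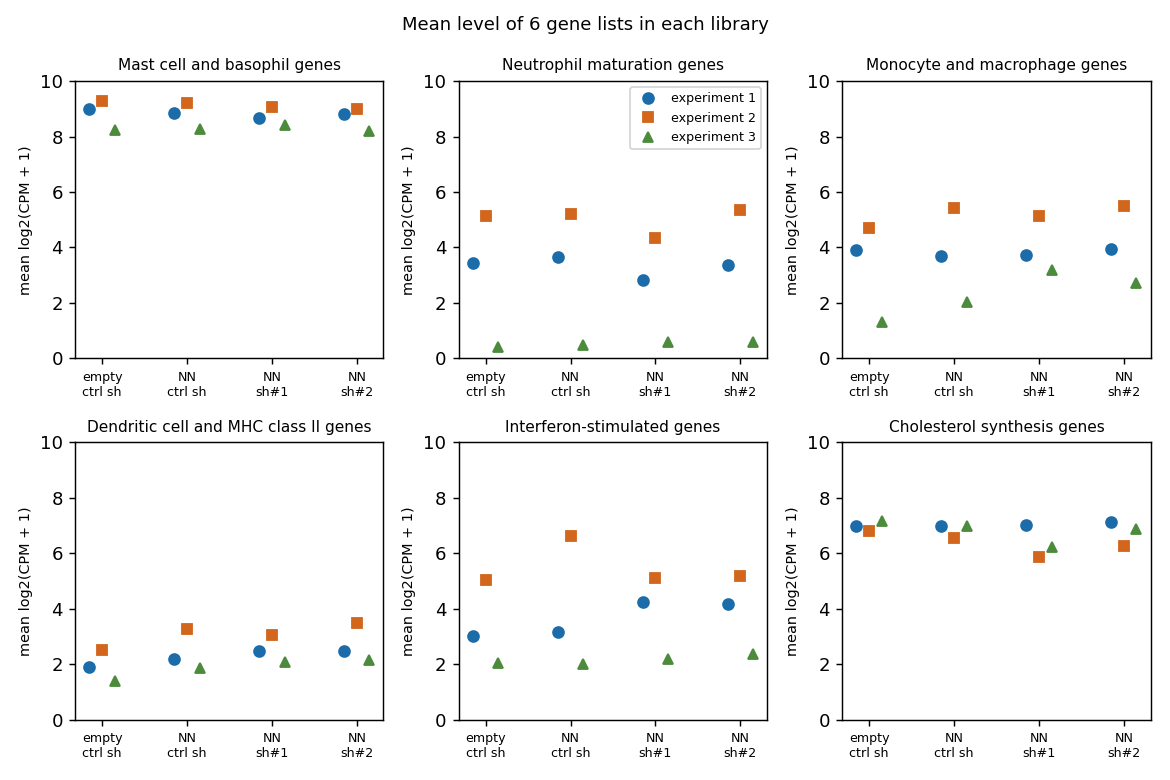
Mean log2(CPM + 1) of 6 gene lists (mast cell, neutrophil, monocyte, dendritic cell and MHC class II, interferon-stimulated and cholesterol synthesis genes) in each of the 12 libraries, by group on the x axis and by experiment in colour and shape, with no error bars because each point is 1 library. Neutrophil genes lay between 0.402 and 0.608 in experiment 3 and between 4.33 and 5.35 in experiment 2, and interferon-stimulated genes reached 6.62 in the fusion library of experiment 2.

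With shNizp1#1 in fusion cells, 7 of 22 neutrophil maturation genes and the eosinophil genes Epx and Prg2 were called lower than with the control shRNA in the blocked fit. Neither list passed with an estimated correlation (adjusted p = 0.446 for both) or without the block (0.381 and 0.490). Of the 22 neutrophil genes 20 lay below 0 in the blocked fit, with a median log2 fold change of -1.24, and 11 were called lower adjusted over the list alone. In experiment 3, 4 of the 22 were lower, and the list mean in log2(CPM + 1) was 0.608 against 0.470 with the control. The monocyte list, which did not pass with shNizp1#1 (adjusted p = 0.125), was at 3.17 against 2.04 in that experiment, with its member Lyz2 at 986 against 100.1 CPM. The called genes included Camp (-1.72, adjusted p = 0.0114), Ngp (-1.55, adjusted p = 0.00756) and Ltf (-1.51, adjusted p = 0.0247), which encode proteins of secondary granules, and Pglyrp1 (-1.55, adjusted p = 0.0363). Ngp fell from 72.7 to 22.1 CPM in experiment 1 and from 301 to 112 in experiment 2, and was at 0.196 and 0.278 in experiment 3. Eosinophil peroxidase, Epx, changed by -3.35 (adjusted p = 0.0114) and the eosinophil granule protein Prg2 by -2.56 (adjusted p = 0.0247). Both folds rest on few counts. In experiments 1, 2 and 3, Epx was at 0.238, 1.67 and 0 CPM against 2.41, 18.5 and 0.196 with the control. Prg2 was at 1.90, 5.30 and 0 CPM against 7.01, 37.3 and 0.196.

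Genes outside these lists were lower as well. Trip13, an ATPase of the mitotic checkpoint (chromosome 13, 73911347 to 73937784), fell from 25.4 ± 9.70 to 7.84 ± 2.79 CPM (SD, n = 3), a log2 fold change of -1.69 (SE 0.18, adjusted p = 0.00100). Bcap29, a protein of the endoplasmic reticulum, fell from 63.9 ± 12.5 to 19.7 ± 5.99 CPM (-1.69, SE 0.18, adjusted p = 0.00100). Neurogranin, Nrgn, changed by -2.26, the ion channel gene Otop1 by -1.31, and the stefin relatives Stfa2l1, Cstdc4 and Cstdc5 by -2.22, -2.06 and -1.78. In experiment 3, Stfa2l1, Cstdc4 and Cstdc5 were at 0.196, 0.196 and 0.589 CPM with the control and at 0 with shNizp1#1. Hexokinase 2, Hk2, fell from 154 ± 44.5 to 85.0 ± 28.6 CPM (-0.89, adjusted p = 0.00932), while the glucose transporter Slc2a3 rose (0.60, adjusted p = 0.0301). Clec10a, a lectin of antigen-presenting cells, rose from 39.4 ± 21.9 to 155 ± 81.9 CPM (2.02, adjusted p = 0.00857). Higher too were Kalrn (2.35), Nxpe2 (2.29), the desmosomal plakophilin Pkp1 (2.09), Chst1 (1.53), the transcription factor Klf2 (1.49), Rsad1 (1.48), Dmwd (1.39), Npffr1 (1.10), Vwf (0.70) and Pecam1 (0.49).

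The blocked edgeR fit called 61 genes higher and 134 lower with shNizp1#1, 15 and 23 of them with an absolute log2 fold change of at least 1. Without the block edgeR called 0 and 0 (480 genes at an unadjusted p under 0.05), limma-voom 0 and 0, and DESeq2 9 and 41. Each of the 6 omissions of 1 library lowered the blocked counts, to between 7 and 26 higher (7 without control replicate 3) and between 40 and 66 lower. Of the 195 blocked calls, 57, 50 and 47 kept theirs without control replicates 1, 2 and 3, and 78, 58 and 68 without shNizp1#1 replicates 1, 2 and 3. Adgrg3, Bcap29, Chst1, Cstdc4, Pkp1, Trip13 and Zkscan17 were called in all 6, and the other genes named for shNizp1#1 were not. Of the neutrophil genes, 2, 5 and 5 were called without control replicates 1, 2 and 3, and 2, 2 and 6 without shNizp1#1 replicates 1, 2 and 3.

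Cholesterol synthesis genes lay below 0 in 21 of 21 members with shNizp1#1, by a median of -0.43, and 4 were called adjusted over the list alone. Sc5d, a desaturase late in the pathway, was the member called over all genes (-0.53, adjusted p = 0.0400). In experiment 1 the list was at 7.04 with shNizp1#1 against 6.97 with the control, in experiment 2 at 5.86 against 6.55 and in experiment 3 at 6.25 against 7.0 in mean log2(CPM + 1). The neutrophil and the cholesterol lists both had camera adjusted p = 7.27e-11, and adjusted p = 0.446 and 0.561 with an estimated correlation. Stromal genes were higher (median 0.49, adjusted p = 0.00310, and adjusted p = 0.345 with an estimated correlation), with Pecam1 the called member, which megakaryocytes and mast cells also express.

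Immediate early genes were higher with shNizp1#1 (0.25, adjusted p = 5.07e-04), and G2 and M phase genes (-0.21, 8.99e-04), ribosome biogenesis genes (-0.20, 0.00191), p53 targets (-0.12, 0.0485) and eosinophil genes (-0.92, 0.0493) were lower. With an estimated correlation the adjusted p was 0.446 for eosinophil genes and 0.678 for the other 4. These 5 lists lost their calls without single libraries. Immediate early genes did without control replicate 1 (0.164), and ribosome biogenesis genes without shNizp1#1 replicate 2 (0.150). G2 and M phase and eosinophil genes did without control replicate 2 (0.0916 and 0.207) and shNizp1#1 replicate 2 (0.720 and 0.419), and p53 targets without replicates 1 and 2 of either group (0.134 and 0.0962 for the control, 0.197 and 0.412 for shNizp1#1). Without the block, cholesterol (1.11e-08), G2 and M phase (0.00263) and ribosome biogenesis genes (0.0199) passed, and stromal (0.107), p53 (0.146) and immediate early genes (0.248) did not. These unblocked calls rest on the preset correlation, and an estimated one ended 15 unblocked list calls over all comparisons. No other list passed in the blocked fit, with HoxA genes at adjusted p = 0.287, mast cell genes at 0.512 and leukaemia regulators at 0.516. In the B cell list, the median (0.31) and camera (down, 0.382) differed in sign.

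With shNizp1#2 in fusion cells, Fuca2 and Tmem160 were, besides Zkscan17, the genes with the lowest adjusted p. Fuca2, a fucosidase (chromosome 10, 13501001 to 13519035), fell from 120 ± 7.75 to 54.4 ± 0.937 CPM (SD, n = 3), a log2 fold change of -1.14 (SE 0.09, adjusted p = 6.21e-05 blocked and 0.00315 unblocked). Tmem160 (chromosome 7, 16452779 to 16455490) fell from 65.9 ± 3.05 to 24.0 ± 5.95 CPM (-1.48, adjusted p = 3.51e-04). Armc1, Sh3bgrl3, the sorting nexin Snx3 and Bzw1 changed by -1.03, -0.68, -0.64 and -0.47. Higher were Btg2 (1.35), an antiproliferative immediate early gene, Ankrd37 (1.19), Disp2 (1.13), Serpinb2 (1.13), the calcium-binding protein S100a6 (0.88), Rnf149 (0.87), Gpsm1 (0.70), Igfbp5 (0.70) and the survival factor Bcl2 (0.59, adjusted p = 0.0241).

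The blocked edgeR fit called 17 genes higher and 9 lower with shNizp1#2, 4 and 6 of them with an absolute log2 fold change of at least 1. Other blocked settings called more: 369 genes without a filter, 78 with DESeq2 and 342 with only the 2 groups. With only the 2 groups, shNizp1#1 had 130 calls, so which shRNA changed more genes depends on the setting. Without the block edgeR called 0 higher and 1 lower, Fuca2 (285 genes at an unadjusted p under 0.05), limma-voom 0 and 1, and DESeq2 2 and 5. That unblocked call of Fuca2 was lost (0 genes) without shNizp1#2 replicate 1. Omitting any 1 of the 6 libraries lowered the blocked counts to between 1 and 4 higher (1 without control replicate 3) and between 3 and 5 lower, with Fuca2, Tmem160 and Zkscan17 called in all 6 and the other genes named for shNizp1#2 in fewer. Of the 26 blocked calls, 9, 6 and 4 kept theirs without control replicates 1, 2 and 3, and 5, 5 and 7 without shNizp1#2 replicates 1, 2 and 3.

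Immediate early genes lay higher with shNizp1#2 (22 of 26 above 0, median 0.50, camera adjusted p = 3.22e-08), and so did cytokine genes (20 of 22, 0.43, 5.93e-06), megakaryocyte genes (9 of 9, 0.43, 1.13e-04), MHC class II and dendritic cell genes (7 of 11, 0.41, 0.00320) and glycolysis genes (16 of 22, 0.06, 0.00106). Ribosome biogenesis genes lay lower (21 of 22 below 0, median -0.23, 2.59e-06). With an estimated correlation the adjusted p was 0.225 for immediate early genes, 0.463 for ribosome biogenesis genes and 0.206 for the other 4. Stromal genes (0.38, adjusted p = 0.00960), erythroid genes (0.60, 0.0310) and the fusion partner list (0.13, 0.0228) were higher, and S phase (-0.23, 9.42e-04) and G2 and M phase genes (-0.15, 0.00271) lower. With an estimated correlation these had adjusted p = 0.206, 0.311, 0.333, 0.746 and 0.746. Single omissions ended these 5 calls: stromal without shNizp1#2 replicate 3 (0.0908), erythroid with each library left out (0.0635 to 0.384), fusion partners without control replicate 2 and shNizp1#2 replicate 1 (0.121 and 0.133). S phase and G2 and M phase genes lost theirs without control replicate 2 (0.204 and 0.277) and shNizp1#2 replicate 2 (0.0647 and 0.139). Without the block, ribosome biogenesis genes (1.93e-04), immediate early, cytokine, S phase and G2 and M phase genes (0.0123 each) and megakaryocyte and erythroid genes (0.0144 for both) passed. Dendritic cell and MHC class II (0.415), glycolysis (0.211), stromal (0.14) and fusion partner genes (0.203) did not. The unblocked calls were made at the preset correlation, and an estimated one ended 15 such calls over all comparisons. Neutrophil and cholesterol genes did not pass in the blocked fit (medians -0.23 and -0.06, adjusted p = 0.630 and 0.244), nor did HoxA genes (0.691). The interferon list had a median of -0.33 while camera gave the direction as up (0.952).

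The shRNAs were compared to ask which changes they shared. Besides Zkscan17, both lowered Cstdc5 (-1.78 with shNizp1#1 and -1.39 with shNizp1#2) and the complement gene C4a (-1.15 with either). Both raised Vwf, the von Willebrand factor of megakaryocytes (0.70 and 0.91), Aldh3a1 (0.64 and 0.87), Adgrg3 (0.91 and 0.57), Ube3c and Mgat4b. These 5 higher and 3 lower genes in the blocked fit, Zkscan17 itself among them, compare with 0.0865 and 0.101 for independent sets of these sizes. Simulations with no effect gave 0.14 for both directions together. Both comparisons subtract the same control libraries, and the simulations hold no effect of either shRNA, so neither figure is a bound for this sharing. Blocked fits without a filter, with DESeq2 and with only the 2 groups shared more genes, as given under the dependence on processing. The unblocked edgeR fit shared 0 and 0 (480 and 285 genes at an unadjusted p under 0.05), limma-voom 0 and 0, and DESeq2 1 and 1. Omitting any 1 of the 9 libraries lowered the blocked count of shared higher genes to between 0 and 2, with 0 without control replicate 3 and without each shNizp1#2 replicate. Shared lower genes went to 1 in each omission but that of shNizp1#1 replicate 3, which left 3. Across genes, the covariance of both effects was 0.0541 against 0.0357 in the simulations, and r was 0.49 against 0.51. Genes are not independent replicates.

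**Figure D3:**
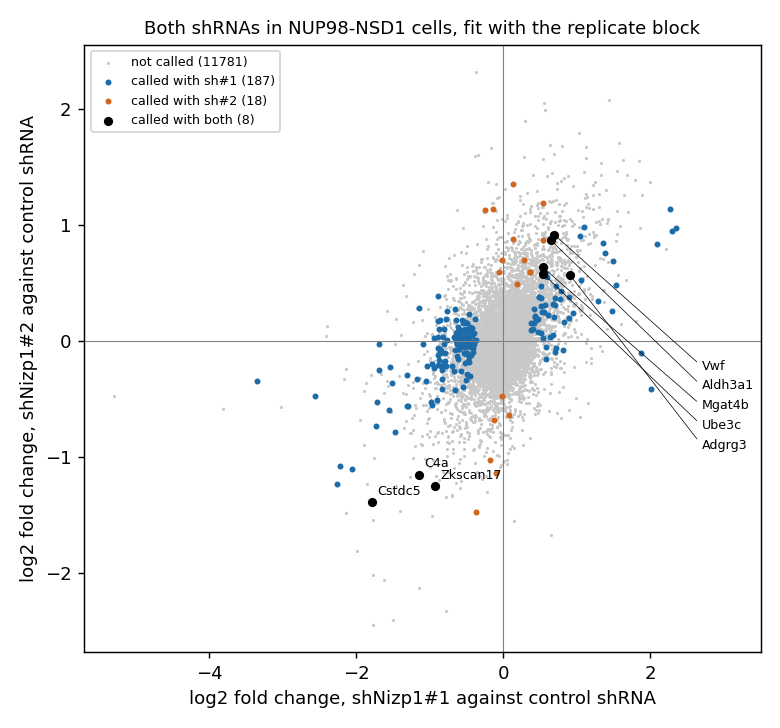
Blocked log2 fold change against the control shRNA with shNizp1#1 (x axis) and with shNizp1#2 (y axis), 1 point per tested gene, n = 3 libraries per group. Blue points (187 genes) were called with shNizp1#1 only, orange points (18) with shNizp1#2 only and black points (8, labelled) with both.

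Between the shRNAs, 22 of 22 neutrophil genes lay above 0 (higher with shNizp1#2) in the blocked fit, with a median of 1.01. The list did not pass with an estimated correlation (adjusted p = 0.711) or without the block (0.430), and in experiment 3 its mean log2(CPM + 1) was 0.582 with shNizp1#2 against 0.608 with shNizp1#1. Called were 5, among them S100a8 (1.01, adjusted p = 0.00387), Camp (1.19), Lcn2 (1.10) and Ngp (0.96), and 11 adjusted over the list alone. All 21 cholesterol genes lay above 0 (median 0.33; Sc5d 0.63). Hk2 was at 199.7 ± 41.0 against 85.0 ± 28.6 CPM (SD, n = 3), a log2 difference of 1.27 (adjusted p = 0.00101). Bcap29 (1.67), Ciita (1.75), the master regulator of MHC class II, Layn (1.57), Fam151a (1.52), the cytokine Il13 (1.45), Epx (3.0), Car2 (1.08), Btg2 (1.22) and Bcl2 (0.65) were also higher. Lower were Clec10a (-2.43), the mast cell protease Mcpt1 (-2.32), Gng7 (-1.49), Pkp1 (-1.26) and Rsad1 (-1.22).

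Between the shRNAs the blocked edgeR fit called 214 genes higher and 70 lower, 31 and 12 of them by at least 1 in log2. Larger blocked counts came from only the 2 groups (1150 genes), no filter (626) and DESeq2 (361). The unblocked fit called 0 and 1, Fuca2 (609 genes at an unadjusted p under 0.05), limma-voom 0 and 1, and DESeq2 58 and 15. The unblocked call was lost (0 genes) without replicates 1 and 3 of either shRNA. Omitting any 1 of the 6 libraries lowered the blocked counts to between 59 and 117 higher (59 without shNizp1#2 replicate 2) and between 10 and 27 lower (10 without shNizp1#2 replicate 3). Bcap29, Bcl2, Clec10a, Fuca2 and Hk2 were called in all 6, and the other genes named for this comparison in fewer. Of the 284 blocked calls, 83, 133 and 119 kept theirs without shNizp1#1 replicates 1, 2 and 3, and 97, 69 and 80 without shNizp1#2 replicates 1, 2 and 3. Camera gave adjusted p = 6.22e-08 for the neutrophil and 1.45e-06 for the cholesterol list, and adjusted p = 0.711 for both with an estimated correlation. Cytokine genes (0.31, adjusted p = 0.0273) and p53 targets (0.16, 0.0282) also passed, with the same adjusted p = 0.711 with an estimated correlation. Without the block, at the preset correlation, cholesterol genes passed (2.84e-05), and cytokine genes (0.369) and p53 targets (0.143) did not. Cytokine genes lost the call without shNizp1#1 replicate 2 (0.337) and shNizp1#2 replicate 3 (0.0657), and p53 targets without shNizp1#1 replicates 1 and 2 (0.0977 and 0.250) and shNizp1#2 replicate 1 (0.134).

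Of the genes raised by the fusion, 1 was called lower with an shRNA. Hoxa9 changed by -0.47 with shNizp1#1 (95% interval -1.05 to 0.10, adjusted p = 0.525) and by -0.14 with shNizp1#2 (-0.69 to 0.41, adjusted p = 0.882), and Hoxa10 by 0.06 (-0.55 to 0.67) and -0.07 (-0.65 to 0.51). Intervals of this width leave room for a decrease of Hoxa9 down to -1.05. Nsd1 (0.26 and -0.09) and Nup98 (0.32 and -0.03) were not called either. Dkk2, raised by the fusion, was at -2.15 with shNizp1#1 (adjusted p = 0.0673) and -1.49 with shNizp1#2 (adjusted p = 0.264). Of the 30 genes raised by the fusion in the blocked fit, shNizp1#1 lowered 1, Lims1 (fusion 0.46, shNizp1#1 -0.42, adjusted p = 0.0218), which was named after its values were seen, and shNizp1#2 lowered 0. Independent sets would share 0.335 and 0.0225 genes. Simulations with no effect gave 0.15 and 0.16 genes called in opposite directions, those lowered by the fusion and raised by the shRNA included. Counted in that way, the data gave 1 and 0. In the unblocked edgeR fit the fusion raised 1 gene, Nsd1, and neither shRNA lowered it (480 and 285 genes at an unadjusted p under 0.05). Reads of the construct can be counted in Nsd1 and Nup98, which are among the 30 genes. Their values with the shRNAs therefore do not test a reversal of the fusion effect, and the unblocked fit offers no other gene for it. Neither DESeq2 nor limma-voom, without the block, found a gene raised by the fusion and lowered by both shRNAs.

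Against the empty vector, 22 of these 30 genes were also raised with shNizp1#1 and 28 of 30 with shNizp1#2, where independent sets would share 0.415 and 0.465. All genes called in the same direction numbered 23 and 28, against 0.10 and 0.11 in simulations. The shRNA groups carry the same fusion and were compared with the same empty-vector libraries, while the simulations hold no fusion effect. A large overlap therefore follows from the design, and these figures do not measure how far the shRNAs left the fusion effect unchanged. The blocked fit called 166 genes higher and 248 lower with shNizp1#1 against the empty vector and 186 and 91 with shNizp1#2, and the unblocked fit called 1 and 0, and 1 and 1 (DESeq2 25 and 48, and 32 and 12). Without shNizp1#1 replicate 3 the unblocked counts were 2 and 1, and without empty-vector replicate 2 that of genes higher with shNizp1#2 was 2. Across genes the covariance of the fusion effect with the shNizp1#1 effect was -0.0392, against -0.0358 in simulations of unchanged groups that share the fusion control libraries, and with the shNizp1#2 effect it was -0.0347 against -0.0358. The differences in covariance were -0.00339 and 0.00106 (SD of the simulations 0.00150 and 0.00141), and the correlations were -0.28 and -0.27, against -0.49 and -0.51. In the unblocked fit the covariances were -0.0468 and -0.0374, against simulated means of -0.0379 and -0.0378. That unblocked shNizp1#1 value lay below the lowest simulated value (-0.0439), and the blocked one did not (-0.0421). Each simulated gene was drawn independently of the others, so the simulated SD and range are too narrow for correlated genes and neither position decides. An opposed effect of shNizp1#1 across genes therefore stays open. For the shRNA groups against the empty vector, the covariances with the fusion effect were 0.126 and 0.130, against 0.0365 and 0.0364 in simulations, which again hold no fusion effect.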

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

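The tests of cell composition and of target dose for the neutrophil genes, the requirement that the seed of an shRNA pass both the experiment and the fusion contrasts by a margin, the comparison of words that share bases with a seed, and the counts of the word by experiment and at matched UTR length were chosen only after the result was seen.

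A direct test found the effects of the shRNAs to differ, which is why these results stand here. With the replicate block, 214 genes were higher and 70 lower with shNizp1#2 than with shNizp1#1. Among the lists, neutrophil maturation genes (camera adjusted p = 6.22e-08) and cholesterol synthesis genes (adjusted p = 1.45e-06) were higher with shNizp1#2, and neither call held with an estimated correlation (adjusted p = 0.711 for both). Without the block, at the preset correlation, the neutrophil list did not pass (camera adjusted p = 0.430) and the cholesterol list did (2.84e-05). An estimated correlation ended 15 of the unblocked list calls over all comparisons.

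For the first pattern, genes lowered with 1 shRNA and not with the other, silencing of other transcripts through the seed of an shRNA is a candidate explanation, and the 3' UTR word most strongly tied to lower values with shNizp1#1 against shNizp1#2 was TGTCATC (t = -10.2, with -10.7 against the control shRNA and -9.21 against the empty vector), beyond the largest absolute t of the experiment contrasts (4.60, the bound named first, set aside for that of the fusion contrast before a result was seen, and computed afterwards), of the fusion contrast (5.40) and of 20 shuffles (4.81). It was among the lowest 3 words in each experiment (t = -8.49, -7.20 and -6.07). It lies in Zkscan17 itself (chromosome 11, 59487194 to 59487200, exon 10, coding sequence), as 21.4% of words do. It occurred in 51 of 127 lowered genes (40.2%, Trip13 and Hk2 among them), against 17.2% at matched UTR length. The word was picked from these same values, so its share and its values by experiment are not separate support. Its t, beyond bounds that are each the largest over all words, goes with a seed effect for part of the lowered genes. For shNizp1#2 the word TCCGCAA (t = -5.29, Zkscan17 exon 6, 59499613 to 59499619, coding sequence) passed the bound named first and not that of the fusion contrast, each by less than the spread of a t. It reached -4.00 against the control shRNA (-1.52, -3.54 and -3.55 in experiments 1, 2 and 3), where the lowest 4 words (-5.03 to -4.24) all hold TCCGCA, and it occurred in 2 of 7 lowered genes (28.6%) against 1.47% of the others (Fisher p = 0.00443, for a word picked from the same values), but GGGTGGG lay as far on the other side (5.48), so a seed effect of shNizp1#2 stays open. The shRNA sequences are not in the labels used here, and a biological difference between the depths of Zkscan17 loss stays open.

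The second pattern is the lower level of neutrophil maturation genes with shNizp1#1. A single library is argued against, since with each library left out at least 2 members were called lower (not always the same ones) and the median lay between -1.05 and -1.38. A smaller share of neutrophil-lineage cells in a mixed culture cannot be told apart from regulation of these genes: 18 of 22 members (81.8%) lay below the control in experiment 1 and 21 of 22 in experiment 2 (medians -1.13 and -1.15), and 4 of 22 in experiment 3, near the floor, which restates the pattern. Nor can loss of Zkscan17, with deeper loss giving a larger decrease, be settled: the median was -0.23 with shNizp1#2, where 16 of 22 members lay below the control in experiment 1 (median -0.40), and neither the list (adjusted p = 0.711 with an estimated correlation) nor Zkscan17 (adjusted p = 0.230) was called between the shRNAs. The word TGTCATC is in the longest 3' UTR of 0 of the 22 members, but other words of that seed and coding sequences were not searched, so an effect of that seed on these genes stays open.

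Other splits of the 6 libraries of a comparison were too few to give a share under 0.05 (10 splits without and 4 with the block). Without the block, the real split called 0 genes in each of the 4 comparisons, and the highest other split called 1 for the fusion and 0 for the others, so that 10 of 10 splits gave as many. With the block, the real split called 10 genes for the fusion, 130 for shNizp1#1, 342 for shNizp1#2 and 1150 between the shRNAs, the highest other split called 0, 0, 2 and 0, and 1 of 4 splits (the real split) gave as many in each comparison.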

How the results depend on the processing

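All alternatives to the blocked fit and the fit of experiments 1 and 2 only were chosen after the result was seen.

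Counts are given as higher and lower genes. For the unblocked fit, the replicate block gave 30 and 3 with the fusion, 61 and 134 with shNizp1#1, 17 and 9 with shNizp1#2, 214 and 70 between the shRNAs, 166 and 248 with shNizp1#1 against the empty vector, 186 and 91 with shNizp1#2 against it, and 5 and 3 with both shRNAs. It brought Zkscan17 past the threshold (-0.93 and -1.25), as did DESeq2 (-0.92 and -1.24). DESeq2 called 8 higher with the fusion, 9 and 41 with shNizp1#1, 2 and 5 with shNizp1#2, 58 and 15 between the shRNAs, 25 and 48 and 32 and 12 against the empty vector, and 1 and 1 with both shRNAs. A fit of only the 2 groups compared gave 0 higher with the fusion, 0 lower with shNizp1#2, 0 lower between the shRNAs, 0 higher with shNizp1#1 against the empty vector and 0 and 0 with shNizp1#2 against it. Without a filter, 1 gene was lower with shNizp1#1, 2 lower with shNizp1#2, 1 higher between the shRNAs, and 2 and 1 and 5 and 3 differed from the empty vector. Against the empty vector, upper-quartile scaling gave 2 higher with shNizp1#1, RLE 3 lower with shNizp1#2 and limma-voom 2 and 3 with shNizp1#2. The cause of these changes was not tested.

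For the blocked fit, no filter gave 280 and 171 with the fusion, 222 and 290 with shNizp1#1, 256 and 113 with shNizp1#2, 437 and 189 between the shRNAs and 73 and 33 with both. Of these fusion calls 448 of 451 were among the genes tested with the filter, so most of the further calls were not the added genes themselves, and the cause was not tested. DESeq2 gave 60 and 16 with the fusion, 48 and 30 with shNizp1#2 and 8 and 7 with both. A fit of only the 2 groups gave 10 and 0 with the fusion, 83 lower with shNizp1#1, 243 and 99 with shNizp1#2, 711 and 439 between the shRNAs and 15 and 11 with both. Without experiment 3, leaving fewer samples, the counts were 2 and 0, 2 and 9, 0 and 4, 10 and 2, and 0 and 0, and the Zkscan17 decrease with shNizp1#1 (-0.88) was no longer called. RLE, upper-quartile scaling, the 1 CPM filter and limma-voom kept these blocked counts within 1.5 times.

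With 1 library left out, the unblocked counts ranged from 0 to 1 lower with shNizp1#2 and between the shRNAs, from 1 to 2 higher and 0 to 1 lower with shNizp1#1 against the empty vector, and from 1 to 2 higher with shNizp1#2 against it. The blocked counts ranged from 4 to 80 higher and 0 to 94 lower with the fusion, 7 to 26 and 40 to 66 with shNizp1#1, 1 to 4 and 3 to 5 with shNizp1#2, 59 to 117 and 10 to 27 between the shRNAs, and 0 to 2 and 1 to 3 with both. Of the 540 blocked fits of named genes with a library left out, 226 kept the call, 314 lost it and 0 turned direction. The list of interferon-stimulated genes in the unblocked fusion comparison turned direction without fusion replicate 2 (adjusted p = 3.71e-04, against 2.60e-12 to 0.536 over its omissions).

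An estimated inter-gene correlation ended 30 of the blocked and 15 of the unblocked list calls. Other settings ended blocked list calls, 9 without a filter, 2 with limma-voom, 4 without experiment 3, and 1 each with RLE, the stricter filter and only the 2 groups. The depth of 3586538 to 6842589 counts limits what can be said of genes near 3 counts, such as Hoxa7 with the empty vector.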

Other observations

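The tests of depth and of cell composition given here for the differences between experiments were chosen only after the result was seen.

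The experiments differed more than the groups did: the replicate number explained 96.9% of the first principal component and the group 1.44%. In experiment 3, all 22 neutrophil maturation genes were lower than in experiments 1 and 2, by medians of -6.29 and -8.33 in log2 (adjusted p = 0.00231 and 0.00600 with an estimated correlation). Cytokine genes were lower by -2.72 and -2.60 (0.0312 and 0.0438) and glycolysis genes by -1.17 and -1.03 (9.63e-04 and 0.00893). Monocyte, eosinophil and primary granule genes had medians of -1.93, -3.86 and -2.38 against experiment 1 and -3.54, -6.48 and -3.99 against experiment 2, most of them without passing at an estimated correlation (eosinophil genes against experiment 2 did, adjusted p = 0.0403). Mast cell genes differed by -0.48 and -0.47. Against experiment 1, 11 of 20 were called lower and 2 higher (camera adjusted p = 1.41e-04, and adjusted p = 0.0993 with an estimated correlation). HoxA genes, which rest on the fusion libraries, were higher in experiment 3 by 1.91 and 3.04 (adjusted p = 0.143 and 0.150 with an estimated correlation). In all, edgeR called 1603 genes higher and 1509 lower in experiment 2 than in experiment 1, 1235 and 1903 in experiment 3 than in experiment 1, and 2906 and 3043 in experiment 3 than in experiment 2.

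A shallower sequencing of experiment 3 is argued against as the cause: its totals ran from 4468392 to 6842589, against a lowest total of 3586538 in experiment 2. After every library was thinned to 3586538 counts the median fold of experiment 3 against the others was 6.93e-04 for neutrophil, 0.146 for monocyte and 0.17 for cytokine genes. Fewer cells of other myeloid types in a mast-cell-rich culture cannot be told apart from regulation of these genes: the highest of the 8 medians of the neutrophil, monocyte, eosinophil and primary granule lists was -1.93, which restates the pattern. Culture time and animal per experiment were not given in the labels used here, and no biological explanation was tested.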
